A study of Rattus norvegicus with 2 samples.

How the data were processed

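HMGB2, a chromatin structural protein of the high mobility group family, was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in neonatal rat ventricular myocytes. These are heart muscle cells taken in primary culture from Sprague Dawley pups of 1 day of age. One library came from untreated (basal) cells and 1 from cells treated with phenylephrine, an alpha-adrenergic agonist that induces hypertrophic growth in such cultures, at 10 µM for 48 h. For the basal cells no such time is given, so whether they were cultured for the same 48 h is unknown here. Per the labels' protocols, the cells were plated for 24 h and fixed in 1% formaldehyde for 10 min, the chromatin was sheared to fragments of 500 bp, and the DNA was sequenced from both ends on an Illumina Genome Analyzer IIx.

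Per the submitters' processing notes, the tools were Bowtie 0.12.7 (an aligner) and MACS 1.4.1 (a peak caller), and the genome build was rn4. The authors deposited 1 peak list per library. Per the file headers each list is a track in bedGraph form, with 4 columns for chromosome, start, end and a score. The score is the deposited significance score of each peak as the authors' peak caller gave it. Its scale is not given in the sources used here. The lowest score in both lists was 50, and 43 basal and 15 phenylephrine peaks carried exactly 3100, with only 3 basal and 2 phenylephrine peaks above that value. The read depth, whether each library was called independently of the other, the use of a control library, the calling threshold and any later filter are not given in the sources used here. The depth behind each peak is therefore unknown, and a score was used only to rank or filter peaks within its own list.

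Peaks were read with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1), and figures were drawn with matplotlib 3.10.9. Starts are printed with 1 added, following the bedGraph convention. The lowest start in both lists is 1, so the files may already count from 1, and every printed start may be 1 bp too high. A peak was called shared when it overlapped a peak of the other list by at least 1 bp. The counts of overlapping peaks were checked against bedtools 2.31.1 and were identical. The observed overlap was set beside 2 kinds of chance placement, each with 1000 draws. In the first, every peak of the other list was placed at random on its own chromosome, from the first base to the end of the last peak in either list. In the second, added after the data were seen, every peak of the other list was shifted by 10 to 100 kb to either side, which keeps the regional density. Random placement also puts peaks into assembly gaps and repeats, which were not masked. The overlap code was tested on simulated data. With 20% of 43721 basal peaks given a true partner it recovered 19.4%, and with 50% it recovered 49.2%. These recovered values are corrected for the overlap of random placements, and the other simulated peaks were placed at random. The shares of shared peaks given below are not corrected in this way.

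Peaks were also counted per chromosome and in 1 Mb bins by their midpoints. Peaks per Mb used the same chromosome spans as the random placement. Shares carry Wilson 95% intervals, bin counts carry exact Poisson 95% intervals, and the interval of a median width is the exact binomial one. All of these cover counting error over peaks only, and neighbouring peaks are not independent. Where 2 such intervals overlap, a difference is not excluded. Ranges given beside random or shifted lists run instead from the lowest to the highest draw. With 1 library per condition there was no replicate, so the spread between cultures is unknown, no test of the treatment was possible and no p-value is given. Every difference below is a difference between 2 libraries.

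The design, the rule for naming regions and most alternatives were fixed before the data were examined. The shifted lists, the 3173 top-scoring peaks of each list, the fixed peak width of 600 bp, the clustering without X and the random placement of peaks scoring at least 100 were added afterwards. The planned design also did not list the top 1% by score, the widths within overlapping pairs or the stretches without peaks. Nor did it list the correlation across bins, the split of bins by total calls, the bins matched to X or the random assignment of calls. By the rule for naming regions the text names the 5 highest-scoring peaks that are shared, basal only or phenylephrine only, and the 5 bins of 1 Mb with the largest difference in each direction. Shared peaks were ranked by basal score, with ties broken by the phenylephrine score. The alternatives were another overlap rule (50% of both peaks, or within 1 kb), a score of at least 100, equal numbers of top-scoring peaks, merged neighbouring peaks, and lists without the widest 1% of peaks or without unplaced and mitochondrial sequence. Gene annotation and genome sequence of rn4 were not used here, because the gene table at hand was of another assembly. Peaks were therefore not assigned to genes, and the planned gene lists, promoter counts, GC content and CTCF motif counts were not analysed here.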

Results

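HMGB2 occupancy was compared between 2 ChIP-seq libraries of neonatal rat ventricular myocytes, 1 from basal cells and 1 from cells given 10 µM phenylephrine for 48 h. The comparison asks where this chromatin protein is found in resting cells and in cells exposed to a hypertrophic agonist. The basal list held 43721 peaks and the phenylephrine list 42691. Both lists covered all 20 autosomes, chromosome X, unplaced sequence (Un) and the mitochondrial genome of rn4. There was no replicate of either condition.

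The 2 libraries gave similar numbers of HMGB2 peaks, but the peaks of the basal library were broader. The median basal peak spanned 1111 bp (95% interval 1105 to 1116), and the median phenylephrine peak 584 bp (583 to 586). The basal peaks covered 56.9 Mb with a mean width of 1302 bp, and the phenylephrine peaks 27.1 Mb with a mean of 636 bp. The difference ran through the whole range of widths. The 5th percentile was 650 bp in the basal list and 385 bp in the phenylephrine list, and the 95th percentile was 2553 bp and 1082 bp. Broad peaks of at least 2 kb made up 11.4% of basal peaks (11.1 to 11.7%) and 0.384% of phenylephrine peaks (0.330 to 0.447%). Within the basal list 32.6% of peaks (32.1 to 33.0%) scored at least 100, and within the phenylephrine list 7.43% did (7.19 to 7.69%). The scores are the authors' own and were given per list, so these shares describe each list and not the strength of binding.

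**Figure D1:**
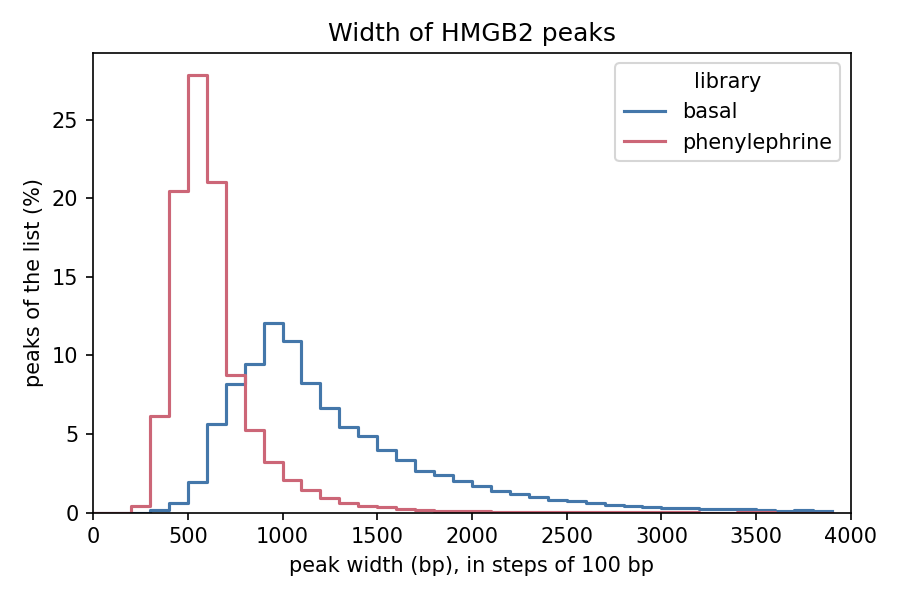
Share of the peaks of each list (vertical axis, %) by peak width (horizontal axis, bp, in steps of 100 bp), for the basal and the phenylephrine library. The phenylephrine distribution lies around its median of 584 bp and the basal one around 1111 bp with a longer tail; the few widths beyond the right edge are not drawn.

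Over the full lists, most HMGB2 peaks were called in 1 library only. A total of 8679 basal peaks, 19.9% (19.5 to 20.2%), overlapped a phenylephrine peak, and 35042 did not. Of the phenylephrine peaks, 8974 overlapped a basal peak, 21.0% (20.6 to 21.4%), and 33717 did not. These shares were 6.34 and 6.55 times those of randomly placed peaks, which averaged 3.13% (2.83 to 3.36% over 1000 draws) for the basal list and 3.21% (2.95 to 3.51%) for the phenylephrine list. Against lists shifted by 10 to 100 kb, which averaged 5.02% (4.73 to 5.34%) and 5.11% (4.80 to 5.39%), they were 3.96 and 4.12 times as high. The overlap depended on the rule. It fell to 8.33% of basal and 8.53% of phenylephrine peaks when at least 50% of both peaks had to overlap, a rule that the difference in width makes hard to meet. Of the peaks scoring at least 100, 37.9% of basal and 57.5% of phenylephrine peaks overlapped any peak of the other list, so most of these phenylephrine peaks were shared. When both lists were held to that score, the shares were 10.6% and 47.7%. The lists then held 14234 basal and 3173 phenylephrine peaks, which limits the basal share. With the 3173 top-scoring peaks of each list the shares were 24.0% and 24.3%.

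At the shared sites the basal peak was usually the broader one. In 95.4% of the 9004 overlapping pairs the basal peak was wider, with a median ratio of 2.00, and in 65.0% of pairs the phenylephrine peak lay wholly inside the basal peak. Shared peaks were wider than unshared ones in both lists. Their median widths were 1488 and 1050 bp in the basal list and 711 and 565 bp in the phenylephrine list.

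Sharing rose with the score of the peak within its own list. Of the lowest-scoring 25% of the basal list, 7.95% of peaks (7.46 to 8.47%) were shared, and of the highest-scoring 25%, 43.1% (42.2 to 44.1%). For the phenylephrine list the values were 14.5% (13.8 to 15.1%) and 36.4% (35.5 to 37.3%). When each list was cut into 4 equal parts by score, every part lay above the highest of its 1000 shifted lists, including the lowest part, where the shifted lists reached at most 4.53% for basal and 5.65% for phenylephrine peaks. Among the top 1% of each list, 370 of 437 basal peaks (84.7%, 81.0 to 87.7%) and 376 of 427 phenylephrine peaks (88.1%, 84.6 to 90.8%) were shared. All 46 basal and all 17 phenylephrine peaks with a score of 3100 or more overlapped a peak of the other list. These counts include unplaced sequence, which supplied 20.0% of the basal and 37.5% of the phenylephrine peaks scoring at least 500.

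**Figure D2:**
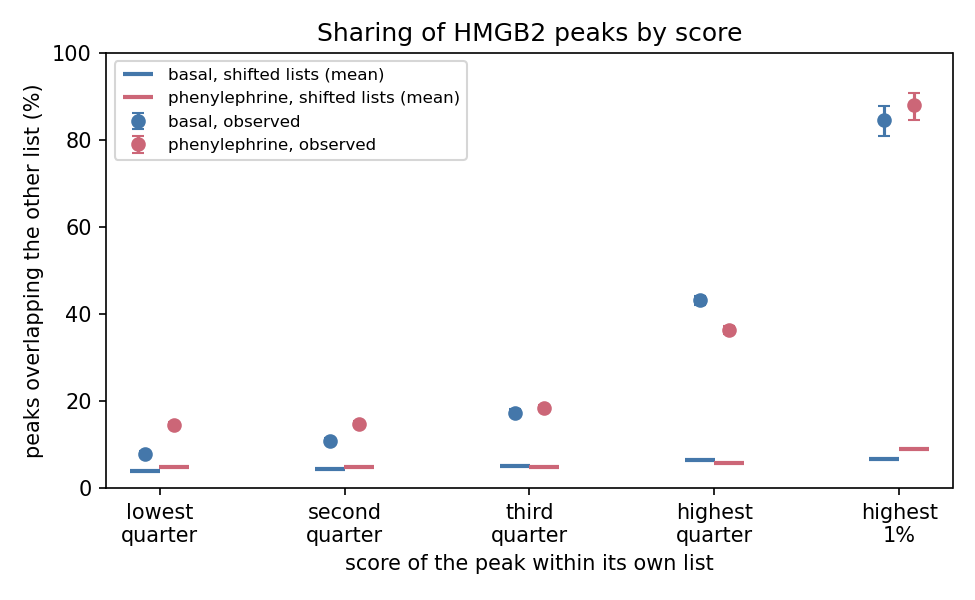
Share of peaks overlapping the other list by at least 1 bp (vertical axis, %) by the score of the peak within its own list (horizontal axis, 4 equal parts and the top 1%). Points are the observed shares with Wilson 95% intervals and dashes are the means of 1000 shifted lists; sharing rises from 7.95% to 84.7% in the basal list and from 14.5% to 88.1% in the phenylephrine list.

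The strongest shared sites by basal score lay on chromosomes 8, 15 and 6 and in unplaced sequence. The highest basal score, 3174, belonged to a peak on chromosome 8 at 104423716 to 104426086, which overlapped a phenylephrine peak at 104423745 to 104425198. The next lay at the start of the chromosome 15 assembly, at 2 to 1071 in the basal list and 4 to 1096 in the phenylephrine list. The third lay in unplaced sequence at 63167981 to 63169221. The phenylephrine peaks at these sites scored 1224, 1335 and 367 within their own list, in this order. The remaining 2 were on chromosome 8 at 34245676 to 34247058 and on chromosome 6 at 91379407 to 91381425, each with a basal score of 3100. They were taken from the 43 basal peaks tied at that score by the phenylephrine score of their partners, 3107 and 3103.

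The strongest sites called in basal cells only lay on chromosomes 5, 12, 3 and 9 and in unplaced sequence. They were chromosome 5 at 107768937 to 107769845 (score 1172), chromosome 12 at 4389686 to 4390475 (score 1170), chromosome 3 at 16982531 to 16984154 (score 1166), unplaced sequence at 74066066 to 74067841 (score 1063) and chromosome 9 at 789927 to 791297 (score 944). The nearest phenylephrine peak lay 30.4 kb from the chromosome 5 site and 21.1 kb from the chromosome 12 site. It lay only 0.574 kb from the chromosome 9 site. The first of these sites ranked 115 in the basal list.

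The strongest sites called in phenylephrine-treated cells only lay on chromosomes 2, 19, 1 and 10 and in unplaced sequence. The first was a broad peak of 5799 bp on chromosome 2 at 243822465 to 243828263 (score 420), 22.9 kb from the nearest basal peak and at rank 94 in its list. The next 3 were narrow, with widths of 266, 228 and 224 bp. They lay on chromosome 19 at 44823177 to 44823442 (score 289), in unplaced sequence at 9467980 to 9468207 (score 284) and on chromosome 1 at 130648944 to 130649167 (score 273). These 3 belong to a group of 43 phenylephrine peaks narrower than 270 bp, a width at which the basal list held 0. In that group 39 peaks scored at least 100, and only 3 of those 39 were shared. Whether such narrow peaks reflect HMGB2 binding was not tested. The last of the named sites was on chromosome 10 at 74850919 to 74853130 (score 255), 0.138 kb from a basal peak.

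HMGB2 peaks were spread unevenly over the chromosomes, in the same broad pattern in both libraries. Chromosome 12 had the highest basal density at 28.0 peaks per Mb, with chromosome 10 next at 26.4, and chromosome 2 the lowest of the autosomes at 12.6. In the phenylephrine list chromosome 10 had 22.4 peaks per Mb, chromosome 12 had 22.1 and chromosome 2 had 13.4. The densest autosome thus exceeded the sparsest 2.22 times in the basal list and 1.67 times in the phenylephrine list. Chromosomes 12, 20 and 10 took smaller shares of the phenylephrine peaks than of the basal peaks. Chromosome 12 held 2.996% of basal peaks (2.84 to 3.16%) and 2.42% of phenylephrine peaks (2.28 to 2.57%). Chromosome 20 held 2.74% (2.59 to 2.89%) and 2.31% (2.17 to 2.46%), and chromosome 10 held 6.69% (6.46 to 6.93%) and 5.80% (5.58 to 6.02%). Over all peaks, chromosome 18 had the highest ratio of the autosomes, 1.12, with 2.996% (2.84 to 3.16%) of basal and 3.34% (3.18 to 3.52%) of phenylephrine peaks. Among peaks scoring at least 100 chromosome 18 held 2.78% and 2.90%, and chromosome 16 held 3.35% and 3.97%, so this ranking did not hold there.

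Chromosome X was poor in HMGB2 peaks in both libraries, and less so in the phenylephrine library. It had 2.32 peaks per Mb in the basal list and 3.80 in the phenylephrine list, against 16.6 and 16.3 per Mb over the autosomes, a deficit of 7.17 and 4.28 times. X held 372 basal peaks, 0.851% (0.769 to 0.941%), and 610 phenylephrine peaks, 1.43% (1.32 to 1.55%), a ratio of 1.68. Among peaks scoring at least 100 the shares were 1.03% (0.873 to 1.20%) and 1.48% (1.12 to 1.96%), and these intervals overlap. Unplaced sequence went the other way, with 1.98% (1.85 to 2.12%) of basal and 1.24% (1.14 to 1.35%) of phenylephrine peaks. That direction turned among peaks scoring at least 100, where the shares were 2.63% and 3.62%. But that score keeps 32.6% of basal and only 7.43% of phenylephrine peaks. Unplaced sequence was also more frequent at high scores in both lists, with 20.0% and 37.5% of peaks scoring at least 500. The turn therefore cannot be read as a difference between the libraries.

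**Figure D3:**
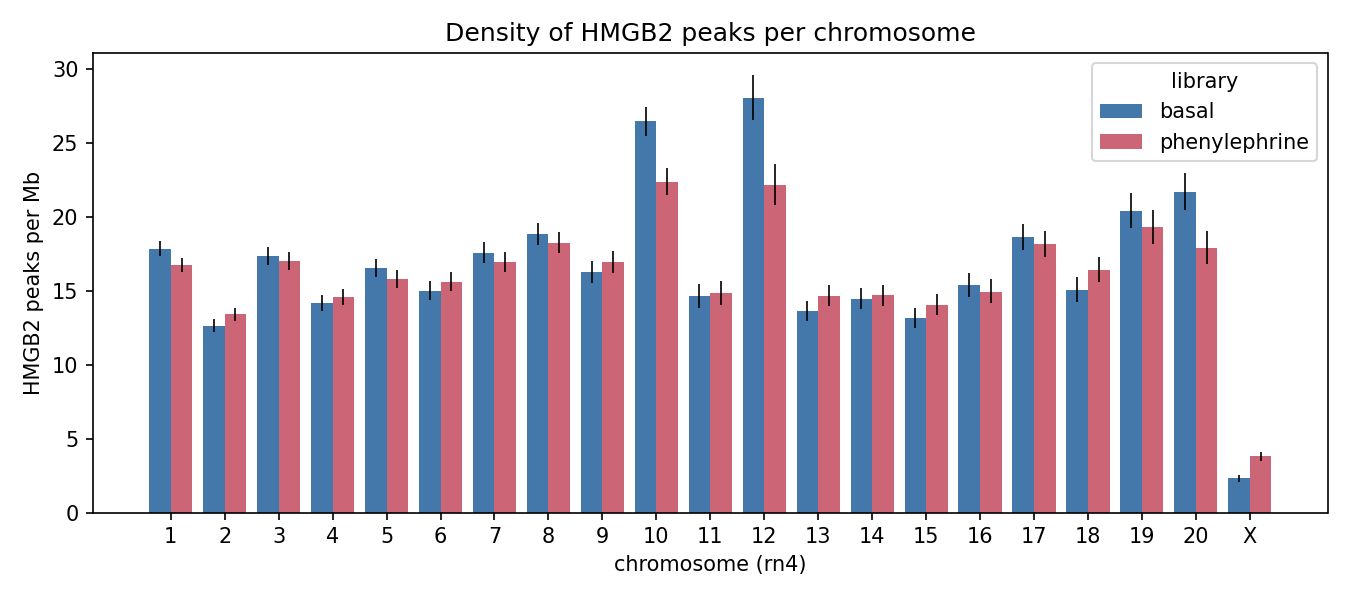
HMGB2 peaks per Mb (vertical axis) on each assembled chromosome of rn4 (horizontal axis) in the basal and the phenylephrine library, with exact Poisson 95% intervals of the counts. Chromosomes 10 and 12 stand highest in both libraries, and X lowest at 2.32 and 3.80 peaks per Mb.

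On the scale of 1 Mb the numbers of peaks in the 2 libraries rose and fell together. Across the 2689 bins of the assembled chromosomes with a peak in either list, the numbers of basal and phenylephrine peaks correlated with Pearson's r = 0.87 and Spearman's rho = 0.89. Within the 144 bins of X alone r was 0.69 and rho 0.64. The correlation is across bins of 1 pair of libraries, and bins are not independent replicates. Regions poor in HMGB2 peaks held relatively more phenylephrine peaks. When the autosomal bins were split into 4 equal parts by their total number of calls, phenylephrine peaks made up 65.4% of calls (63.9 to 66.8%) in the poorest part and 56.7% (55.9 to 57.6%) in the next. They made up 50.0% (49.4 to 50.7%) and 45.1% (44.6 to 45.6%) in the richer parts, and 62.1% (59.0 to 65.1%) on X. With the 21345 top-scoring peaks of each list the poorest and richest parts were at 69.7% (67.5 to 71.8%) and 45.4% (44.7 to 46.1%). With the 3173 top-scoring peaks, a number chosen after the data were seen, they were at 56.3% (49.8 to 62.5%) and 48.6% (46.8 to 50.3%), with overlapping intervals.

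**Figure D4:**
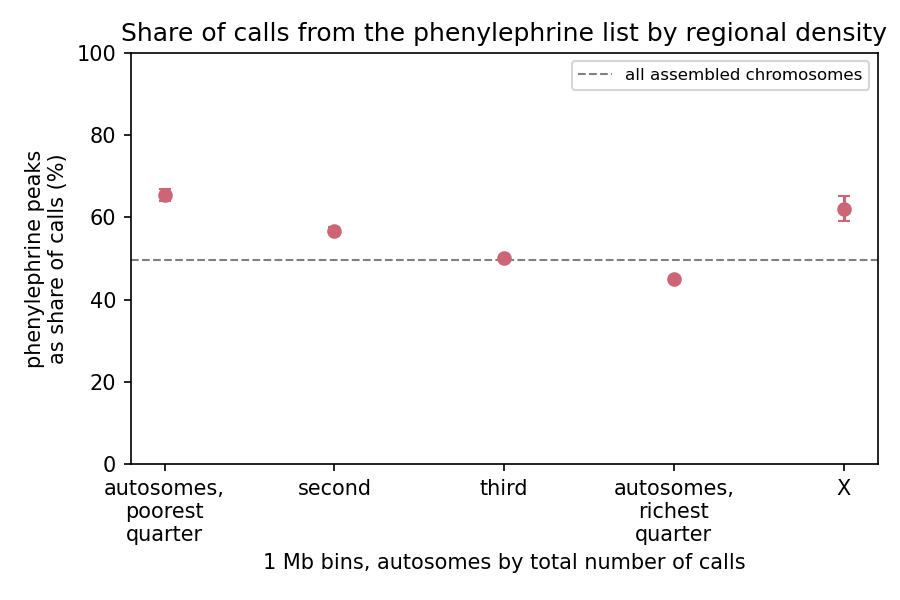
Phenylephrine peaks as a share of all calls (vertical axis, %, with Wilson 95% intervals) in 1 Mb bins of the autosomes, split into 4 parts by their total number of calls, and in the bins of X (horizontal axis). The share falls from 65.4% in the poorest to 45.1% in the richest part, and X stands at 62.1%; the dashed line is the share over all assembled chromosomes, 49.6%.

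The regions with the largest excess of phenylephrine over basal calls lay on chromosomes 3, 18, 8 and 11. In the bin of chromosome 3 at 150000001 to 151000000 there were 2 basal peaks (95% interval 0.242 to 7.22) and 23 phenylephrine peaks (14.6 to 34.5). On chromosome 3 at 100000001 to 101000000 there were 4 basal peaks (1.09 to 10.2) and 23 phenylephrine peaks. The bin of chromosome 18 at 48000001 to 49000000 held 12 basal and 31 phenylephrine peaks, and that of chromosome 11 at 11000001 to 12000000 held 8 and 25. The bin of chromosome 8 at 75000001 to 76000000 held 15 (8.40 to 24.7) and 34 (23.5 to 47.5), with overlapping intervals.

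The regions with the largest excess of basal over phenylephrine calls lay on chromosomes 3, 5 and 20. The bin of chromosome 3 at 143000001 to 144000000 held 64 basal peaks (49.3 to 81.7) and 35 phenylephrine peaks (24.4 to 48.7). On chromosome 5 the bin at 142000001 to 143000000 held 50 and 21, the bin at 167000001 to 168000000 held 53 and 24, and the bin at 151000001 to 152000000 held 53 and 26. On chromosome 20 the bin at 6000001 to 7000000 held 58 and 30. Of the 2689 bins, the intervals of the 2 counts lay apart in 13 with more basal peaks and in 20 with more phenylephrine peaks. How many bins would lie apart by chance was not estimated, and the named bins are the extremes of these same bins.

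Peaks of 1 library alone filled few whole bins. There were 154 bins with phenylephrine peaks only, 47 of them on X, and 17 bins with basal peaks only, 5 of them on X. When each call was assigned to a library at random, the means over 1000 draws were 60.6 bins (at most 83) and 63.4 bins (at most 87). The bins with phenylephrine peaks only held up to 12 peaks, and those with basal peaks only up to 4. Among peaks scoring at least 100 the direction turned, with 87 bins for phenylephrine and 702 for basal, since the phenylephrine list then held 3173 peaks and the basal list 14234.

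HMGB2 peaks lay closer together than random placement gave in both libraries. Random placement does not keep the regional density, so the values cannot separate local clustering from uneven density over larger regions. In the basal list 46.3% of peaks (45.8 to 46.7%) had another basal peak within 10 kb, against 31.7% (30.9 to 32.7%) in 1000 random placements. In the phenylephrine list 35.4% (35.0 to 35.9%) did, against 29.1% (28.3 to 30.0%). Among the fewer peaks scoring at least 100 the shares were 20.3% (19.7 to 21.0%) for basal peaks, against 12.3% (11.0 to 13.4%) at random, and 6.62% (5.80 to 7.54%) for phenylephrine peaks, against 2.64% (1.51 to 4.16%).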

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

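With 1 library per condition no library could be left out, and no alternative here tests the treatment. No paired analysis was possible because each condition has 1 library. The intended alternatives on gene features, promoter windows, gene lists and sequence content were not run, since no annotation or sequence of rn4 was used. The cause of the shifts below was not tested beyond what each setting removes. The alternatives with the 3173 top peaks, with a fixed width and without X were chosen after seeing the data. What limits all values is that the read depth is unknown and that scores cannot be compared between the lists.

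With a score of at least 100 the basal list kept 14234 peaks (median width 1540 bp, 24.4 Mb) and the phenylephrine list 3173 (838 bp, 2.96 Mb), so basal peaks stayed the wider ones. Merging peaks within 1 kb gave medians of 1129 and 588 bp and 57.5 and 27.6 Mb. Leaving out unplaced and mitochondrial sequence gave 55.9 and 26.8 Mb.

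The share of basal peaks overlapping a phenylephrine peak was 8.33% with 50% of both peaks, 24.7% within 1 kb, 10.6% with a score of at least 100 in both lists and 37.9% with that score asked of the basal peak only. It was 21.5% with 21345 and 24.0% with 3173 top peaks per list, 18.8% without the widest 1%, and 16.7% with every peak set to 600 bp. For phenylephrine peaks the values under these settings were 8.53%, 25.8%, 47.7%, 57.5%, 21.9%, 24.3%, 19.9% and 17.3%. Within 1 kb, the lowest- and highest-scoring 25% reached 13.1% and 47.0% in the basal list and 19.7% and 40.4% in the phenylephrine list, so sharing rose with score under both rules.

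By covered length, X held 0.767% of the basal and 1.26% of the phenylephrine list, and unplaced sequence 1.84% and 1.36%. With a score of at least 100, X held 1.03% of basal peaks, and unplaced sequence 2.63% of basal and 3.62% of phenylephrine peaks. This turns that direction, but the score keeps unlike parts of the 2 lists, so the turn cannot be read between the libraries. Peaks with a neighbour within 50 kb made up 89.2% and 85.5%. Within 10 kb the shares were 20.3% and 6.62% at a score of at least 100, and 42.8% and 32.2% after merging. Bins with peaks of 1 list only numbered 702 for basal and 87 for phenylephrine at that score, which also turns the direction.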

Other observations

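The tests of moved peaks for most unshared peaks, of sex makeup and of all 3 explanations of the peak width were chosen after the result was seen. Long stretches without HMGB2 peaks were more frequent in the basal library. The basal list left 262 stretches of at least 1 Mb between neighbouring peaks, 455 Mb in total, and the phenylephrine list 122 stretches and 180 Mb. Of the phenylephrine stretches 73.8% by length also lay inside basal stretches, while 1430 phenylephrine peaks lay inside basal stretches and 197 basal peaks inside phenylephrine stretches. X held 37 of the basal stretches, 99.8 Mb, and 36 of the phenylephrine stretches, 59.8 Mb. The longest in both lists lay on X, from 109834676 to 121109833 in the basal list (11.3 Mb) and from 109924888 to 114739107 in the phenylephrine list (4.81 Mb). What sequence these stretches hold, assembly gaps included, was not examined.

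The mitochondrial genome carried 1 peak in each list at nearly the same place, 6 to 1596 in the basal list (score 436) and 2 to 1589 in the phenylephrine list (score 392). Unplaced sequence supplied 74 of the 370 basal peaks scoring at least 500 (20.0%, 16.2 to 24.4%) and 30 of the 80 such phenylephrine peaks (37.5%, 27.7 to 48.5%). The phenylephrine list held 43 peaks narrower than 270 bp and the basal list 0. Of these 43 peaks, 39 scored at least 100 and 3 of those 39 were shared.

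The first pattern is the width of the peaks, and its explanations stay open. Stronger peaks were wider within each list, from a median of 906 to 1630 bp between the lowest- and highest-scoring 25% of basal peaks and from 572 to 669 bp in the phenylephrine list. If this were the cause, the lowest-scoring 25% of basal peaks should be no wider than the median phenylephrine peak of 584 bp. At 906 bp they were wider, so that outcome was not met. But the scores cannot be compared between the lists and the depth is unknown, so stronger signal in the basal library remains a candidate explanation. Longer DNA fragments or another setting of the peak caller in 1 library is another. The width ratio of at least 1.69 at the 5th, 50th and 95th percentiles is the pattern itself and does not count for it. A narrower occupancy of the same sites after phenylephrine cannot be told apart from these, because the basal peak was wider in 95.4% of overlapping pairs under any of them and each condition has 1 library.

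The second pattern is that few single peaks were shared while the numbers of peaks per 1 Mb bin were correlated. If unsteady calls near the calling threshold were the whole cause, nearly all of the strongest peaks should be shared. The values for the top 1% were 84.7% (81.0 to 87.7%) of basal and 88.1% (84.6 to 90.8%) of phenylephrine peaks, unplaced sequence included. Both lay between the bounds set for either outcome (90% and 75%), so this stays open. Only 23.3% of unshared basal peaks had a phenylephrine peak within 5 kb, and 22.6% of unshared phenylephrine peaks had a basal one. These shares argue against a move within 5 kb for most unshared peaks. The basal share still lay above the highest of the shifted lists, 22.8%, so a move of some peaks stays open. Its excess over the mean of the shifted lists was 1.09 percentage points within 5 kb and 2.57 points within 10 kb. Whether this excess reflects moved peaks or finer local density stays open. Longer moves cannot be judged, because the shifted lists themselves move peaks by 10 to 100 kb. A change of sites by phenylephrine was not tested, as it would need replicates.

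The third pattern is the relative excess of phenylephrine calls on X and in peak-poor regions. Phenylephrine peaks made up 62.1% of calls on X, against 62.4% (59.0 to 65.8%) in autosomal bins matched on their total calls, so X differed from them by -0.30 percentage points while it stood 12.5 points above the genome. This is consistent with a lower contrast between rich and poor regions over the whole genome, and argues against a different sex makeup of the pups, which the labels do not give, as the whole cause on X. The part of low-scoring calls stays open. On X, phenylephrine peaks scoring at least 100 had a share of 1.48% (1.12 to 1.96%), above the interval of all basal peaks (0.769 to 0.941%), but that bound set strong peaks against peaks of all scores. Basal peaks of such scores had 1.03% (0.873 to 1.20%), an overlapping interval. Phenylephrine peaks made up 292 of the 502 X calls (58.2%, 53.8 to 62.4%) with 21345 top peaks per list, and 47 of 81 (58.0%, 47.2 to 68.2%) with 3173. On the autosomes the poorest bins exceeded the richest by 24.3 points with the 21345 top peaks. But that part of the phenylephrine list still reached down to a score of 62.3. With 3173 top peaks the gap was smaller, 7.69 points, and the overlap of its intervals does not show it to be absent. Whether the lower contrast comes from the treatment or from a less enriched library was not tested.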
